A study of Mus musculus with 8 samples.

How the data were processed

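RNA was measured in 8 libraries of mouse pluripotent stem cells, 2 each of the derived lines CDGC1 and CDGC6, of control E14tg2a ES cells and of Dnd1-KD ES cells. Per the labels, cells grew in serum and LIF, total RNA was taken with RNeasy columns, and TruSeq RNA v2 libraries were run on an Illumina HiSeq2500. The deposited FPKM values, per the file headers, come from Cufflinks gene tracking tables made for 1 library each, as fragments scaled to transcript length and mapped fragments, with an interval around each value. The authors' notes name TopHat2, Bowtie, Cufflinks, Cuffdiff and mm10 but give neither versions nor roles. Each table also holds transcripts assembled without a gene name.

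Each file was read as deposited. Symbols that any library's table joined into 1 entry were treated as 1 unit in all 8 libraries, with FPKM summed over its entries. Spreadsheet dates in place of gene names were read back for 26 names, and GENCODE vM21 placed the gene of 25 of them on the same chromosome. Entries without a gene name held 76.8% to 85.6% of the summed FPKM of a library and were not used in the comparisons. Small RNA genes were removed. Units with at least 1 FPKM in at least 2 of the 8 libraries were tested, 11905 in all, of which 661 hold more than 1 symbol and 646 are listed at 0 in at least 1 library. Because fragments over a shared stretch can be given to 1 of 2 overlapping genes, exact zeros were compared between the libraries of a group. Genes at 0 in 1 library and at least 5 FPKM in the other numbered 62 in CDGC1, 61 in CDGC6, 56 in control and 63 in Dnd1-KD. Their loci overlapped another gene in 59.7%, 68.9%, 66.1% and 69.8% of cases, against 23.2%, 22.9%, 22.8% and 22.7% of the genes with at least 5 FPKM in both libraries of the group (two-sided Fisher's exact test, p = 9.69e-10, 4.41e-14, 7.71e-12 and 3.60e-15). Such zeros can be failed estimates.

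Read counts are not in the files. The fragments behind a value were derived from its FPKM and the file's interval, and summed to 10.7 M to 18.0 M per library. Of the implied fragment numbers below 60, 40.5% to 42.5% lay within 0.02 of a whole number, so counts could not be recovered and count models were not used. The log ratio between the 2 libraries of a group, centred on its median, was set against the spread that both intervals imply together. It went beyond that range in 56.9% of genes in CDGC1, 48.7% in CDGC6, 41.0% in Dnd1-KD and 18.5% in control, where chance gives 5%. Only entries of a single symbol with many implied fragments in both libraries were used, 8921 to 9568 genes per group.

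Groups were taken from the labels. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 8 libraries, eBayes with trend, two-sided) on log2(FPKM + 1), with Benjamini-Hochberg adjustment over all units tested and a threshold of 0.05. The 5 comparisons were Dnd1-KD, CDGC1, CDGC6 and the mean of both derived lines against control, and CDGC1 against CDGC6. Each of 21 gene lists was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 21 lists, and again with an estimated correlation and with fry. Member counts cover only units that passed the filter. These were 13 for the 26 2-cell-like genes listed, 6 for 39 Hox genes, 5 for 20 testis somatic genes and 4 for 18 leukocyte genes. The filter could be met by the 2 libraries of 1 group alone. Groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. By that rule each comparison names Dnd1, Ezh2 and Ccnd1. It also names the 10 largest rises and 10 largest falls that passed with non-overlapping libraries and a mean of at least 1 FPKM in the higher group, predicted and clone-named genes left out, and up to 4 members of each list with the smallest p. The 10 largest rises and falls among genes with no library at 0, the genes drawn in the plot of expression by library, and genes marked in the text were added after the values were seen. On simulated data with 200 changed units of 11905, 2-fold changes were recovered in 55.5% to 75.0% of units and 4-fold changes in 83.0% to 88.0%, depending on the comparison. Far more units passed in the real data, where the adjusted threshold is less strict, so these shares do not carry over.

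Overlap between comparisons that share the control libraries was set against 100 simulated data sets of unchanged groups. Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, quantile normalization, median-ratio scaling, only the compared groups in the fit, the replicate number as a block, eBayes without trend, the highest entry per gene, small RNA genes kept, a 2-fold minimum, and each library left out in turn. Alternatives added after the data were seen were exact zeros at overlapping genes set to missing, units of 1 symbol only, and the control libraries averaged as 1 sample. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used to read files and draw figures.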

Results

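RNA of mouse pluripotent stem cells was sequenced in 8 libraries, 2 for each of 4 groups. CDGC1 and CDGC6 are 2 stem cell lines that were made from teratoma cells arising in the testis of new-born mice homozygous for the ter mutation of Dnd1. Dnd1 encodes an RNA-binding protein of the germ line, and mice that lack it are known for testicular teratomas on 129 backgrounds. Both lines carried an Oct4 reporter transgene (Oct4deltaPE-GFP) on the 129Sv background and were at passages 15 to 18. The control was E14tg2a, a wild-type embryonic stem (ES) cell line from 129/Ola embryos that is known to lack a working Hprt gene, at passages 10 to 12. The Dnd1-KD ES cells, in which Dnd1 was knocked down, were at the same passages as the control. All cells grew in medium with serum and the cytokine LIF.

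Expression is given as FPKM (fragments scaled by transcript length and library size), as mean ± SD over the 2 libraries of a group. Differences between groups are log2 differences of FPKM + 1 with their standard error (SE), and an adjusted p comes from limma with Benjamini-Hochberg adjustment. The files hold no read counts. Their own intervals implied 11.9 M and 13.3 M fragments behind the CDGC1 libraries, 13.1 M and 12.8 M for CDGC6, 18.0 M and 12.6 M for control, and 17.7 M and 10.7 M for Dnd1-KD. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measured only the spread between these libraries, which may be technical. Derivation, strain, genotype and passage differed together between the derived lines and the control ES cells, and no comparison here separated them.

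The targeted gene came first. Dnd1 lies on chromosome 18 at 36763671 to 36766214 (mm10, minus strand), where its end overlaps that of Wdr55 on the other strand. Hars, on the same strand as Dnd1, ends just upstream of it. Dnd1 was listed at 0 in both control libraries and in all 4 libraries of the derived lines. In the Dnd1-KD libraries the files joined Dnd1 and Hars, a histidyl-tRNA synthetase, into 1 entry of 57.6 and 53.9 FPKM, so Dnd1 had no value of its own there either. The joint Dnd1 and Hars value was 65.4 ± 0.525 FPKM (SD, n = 2) in control and 55.7 ± 2.65 FPKM in Dnd1-KD, a log2 difference of −0.23 ± 0.08 that did not pass the test (adjusted p = 0.0728), though it passed without the first or the second CDGC1 library (0.0360 and 0.0359) and with only the compared groups fitted (0.0353). These files therefore hold no measurement of the knockdown, and the group is named by its label throughout. Hprt, a purine salvage enzyme on chromosome X at 52988137 to 53021659, was at 0.407 ± 0.0682 FPKM in control and 0.588 ± 0.0772 FPKM in Dnd1-KD, against 123 ± 1.64 FPKM in CDGC1 and 128 ± 7.40 FPKM in CDGC6. These Hprt values matched the E14tg2a label of the control and placed the Dnd1-KD libraries with it.

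**Figure D1:**
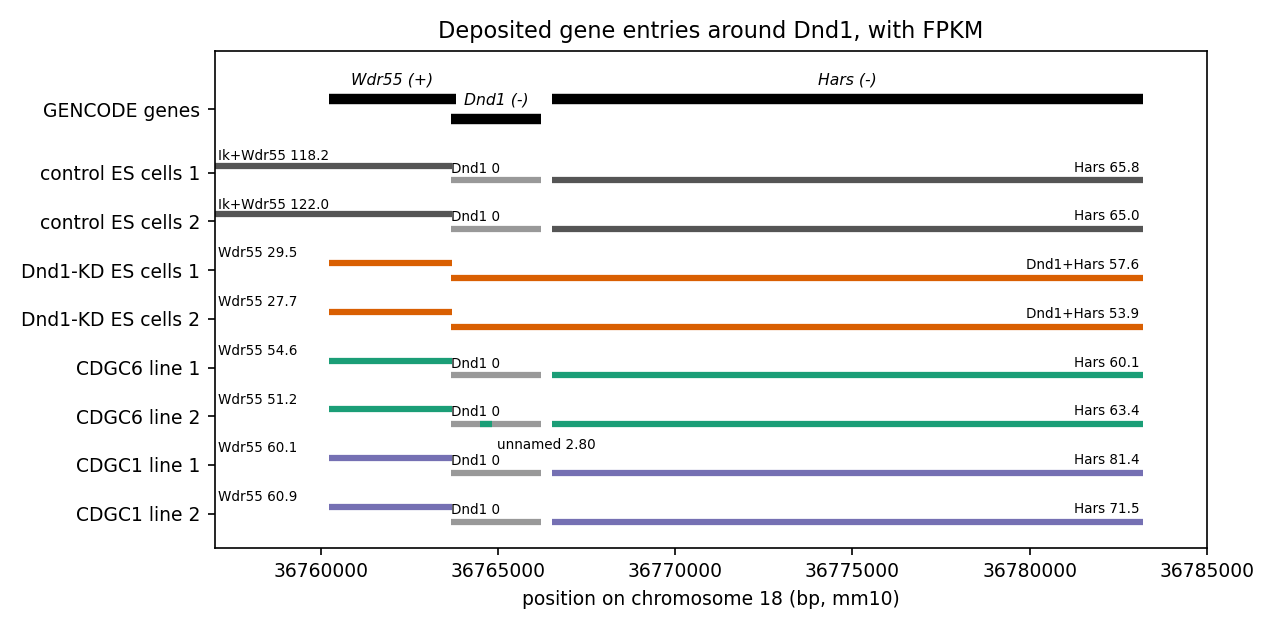
Entries of each deposited table along chromosome 18 (horizontal axis, position in base pairs, mm10) around Dnd1, each with its FPKM, 1 line of entries per library, under the GENCODE genes with their strand. Dnd1 is listed at 0 in 6 libraries and joined with Hars in both Dnd1-KD libraries (57.6 and 53.9 FPKM), while Hars has an entry of its own in the other 6, and 1 CDGC6 library has an unnamed transcript at 2.80 FPKM within it.

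The 8 libraries separated by group. The first principal component, with 53.1% of the variance, set CDGC1 (scores of −73.3 and −72.9) apart from the other 6 libraries (3.98 to 40.2). The second, with 23.0%, set Dnd1-KD (36.4 and 41.8) apart from CDGC6 (−35.4 and −39.9), with control between them (−14.7 and −13.6). Pearson's r across genes was 0.979 within CDGC1, 0.977 within CDGC6, 0.984 within control and 0.979 within Dnd1-KD, against 0.853 to 0.956 between groups. Genes are not independent replicates, so these coefficients only describe the libraries.

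Knockdown of Dnd1 in ES cells asks what the gene does in pluripotent cells outside the germ line. In the Dnd1-KD libraries 17 of 28 pluripotency genes and 16 of 32 hypoxia and glycolysis genes were lower than in control. Higher were 13 of 13 tested 2-cell-like genes (26 listed), 14 of 24 p53 response genes and the HSP70 genes Hspa1a and Hspa1b. None of these lists passed with an estimated inter-gene correlation. Pou5f1, the central POU factor of pluripotency, was at 494 ± 52.7 FPKM in Dnd1-KD (SD, n = 2) against 939 ± 7.07 FPKM in control (log2 difference −0.93 ± 0.11, adjusted p = 0.00292). Mdm2, which limits p53 and is itself induced by it, rose from 96.7 ± 1.68 to 231 ± 17.8 FPKM (1.25 ± 0.10, adjusted p = 0.00112). The joint value of Hspa1a and Hspa1b, near-identical genes of the inducible heat shock protein HSP70 that reads cannot tell apart well, rose from 45.4 ± 10.2 to 487 ± 191 FPKM (3.35 ± 0.30, adjusted p = 0.00149).

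Of the naive and general pluripotency list, 17 of 28 measured members fell and 1 rose in Dnd1-KD (18 and 1 adjusted over the list alone). Camera gave the list an adjusted p = 9.33e-06 with the preset correlation and an adjusted p = 0.496 with an estimated correlation. Besides Pou5f1, Tdgf1, a co-receptor of NODAL, went from 243 ± 12.9 to 90.9 ± 29.4 FPKM (−1.45 ± 0.21, adjusted p = 0.00472). Sox2 went from 163 ± 6.81 to 87.6 ± 15.3 FPKM (−0.90 ± 0.14, adjusted p = 0.00570). The primed or epiblast list had 12 of 22 members lower and 1 higher (12 and 2 adjusted over the list alone). The camera adjusted p was 0.000436, and adjusted p = 0.429 with an estimated correlation. Its members Pou3f1 (−1.27), Lef1 (−1.27) and the DNA methyltransferase Dnmt3b (−1.31) each lost more than 1 log2 unit, while the cadherin Cdh2 rose (1.20 ± 0.17, adjusted p = 0.00492). Of the germline list 8 members fell and 5 rose among 28 (8 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0548). It passed with quantile normalization (adjusted p = 0.0289), with exact zeros at overlapping genes left out (0.0274), and without the second control library (0.0313) or the second Dnd1-KD library (0.0299). Ifitm3, a surface protein of early germ cells, fell in that list (−0.70 ± 0.10, adjusted p = 0.00398). The meiotic cohesin gene Rec8 was listed at 0 in both Dnd1-KD libraries, which can be a failed estimate, and stood at 4.70 ± 0.0498 FPKM in control.

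All 13 tested members of the 2-cell-like list rose in Dnd1-KD (13 adjusted over the list alone). The list holds 26 genes, and those below the filter were not tested. It passed camera with an adjusted p = 1.22e-06, against an adjusted p = 0.429 with an estimated correlation. These genes mark a rare ES cell state that resembles the embryo after its first cleavage, and most belong to families of near-identical copies, so the value of any single copy is uncertain. Zscan4f rose from 9.70 ± 0.878 to 28.1 ± 2.68 FPKM (1.44 ± 0.20, adjusted p = 0.00444). Tcstv3 rose from 2.02 ± 0.0612 to 5.18 ± 0.424 FPKM (1.03 ± 0.09, adjusted p = 0.00138), and Gm8300 from 4.24 ± 0.164 to 11.1 ± 1.23 FPKM (1.20 ± 0.14, adjusted p = 0.00262). In the p53 response list 14 of 24 members rose and 1 fell (16 and 2 adjusted over the list alone). Camera gave an adjusted p = 0.000436, and an adjusted p = 0.429 with an estimated correlation. The CDK inhibitor Cdkn1a rose from 27.8 ± 1.38 to 86.3 ± 9.18 FPKM (1.60 ± 0.16, adjusted p = 0.00184). The death receptor gene Tnfrsf10b rose from 16.5 ± 0.050 to 35.1 ± 2.82 FPKM (1.04 ± 0.10, adjusted p = 0.00187). The member that fell was Trp53 itself, named here after its values were seen (−0.35 ± 0.06, adjusted p = 0.00852). Among the largest rises of genes with no library at 0 were Gadd45g (2.14 ± 0.23, adjusted p = 0.00216) and Herpud1, a component of protein quality control at the endoplasmic reticulum (2.07 ± 0.22, adjusted p = 0.00216). Ddit3 and Atf5, transcription factors of the integrated stress response, were listed at 0 in the other 6 libraries and at 135 and 180.5 FPKM and 48.1 and 58.2 FPKM in the 2 Dnd1-KD libraries. Zeros in these files can be failed estimates, so whether and how far these 2 genes rose is uncertain.

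**Figure D2:**
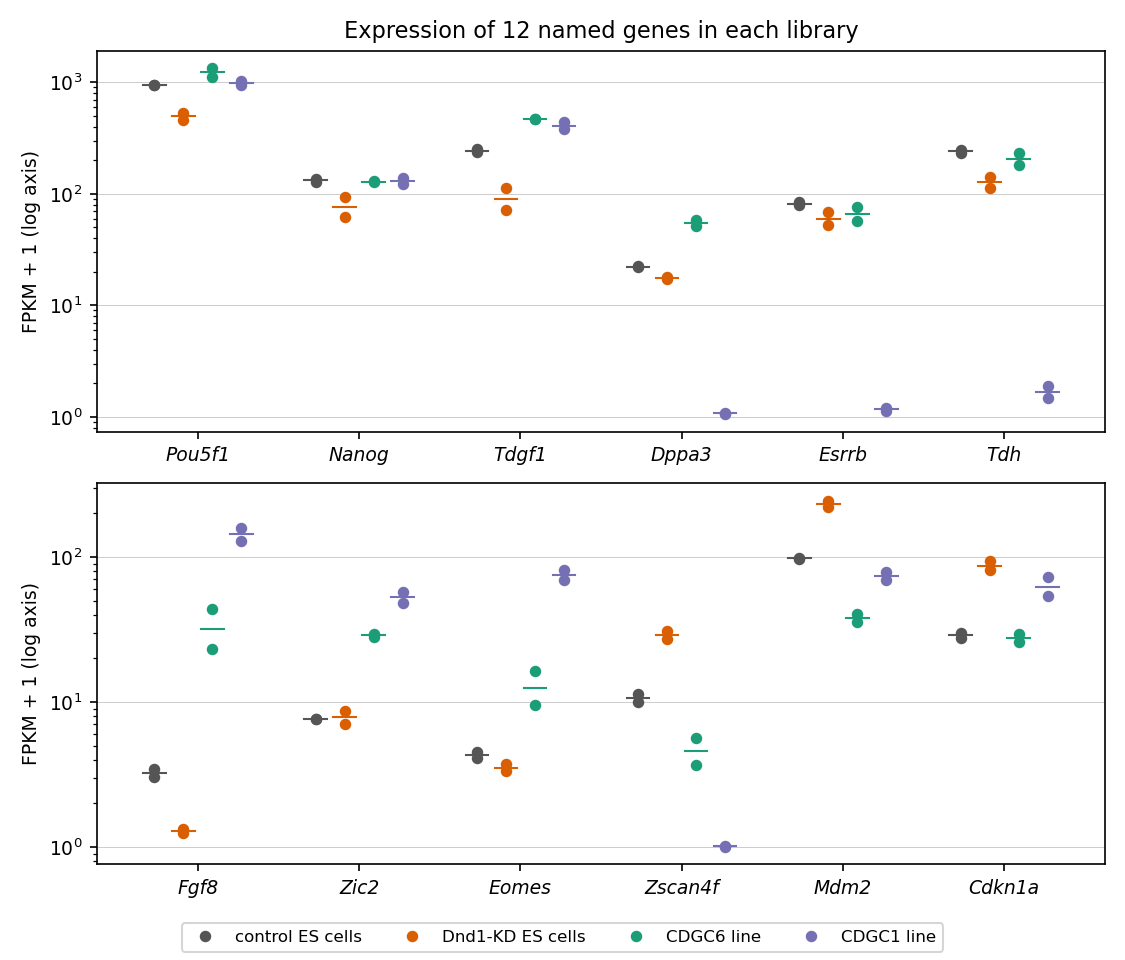
Expression of 12 named genes in each library (vertical axis, FPKM + 1 on a log axis), 1 point per library and a line at the group mean of the log values, with colours for control ES cells, Dnd1-KD ES cells, CDGC6 and CDGC1. Pou5f1 and Nanog stay high in CDGC1 while Dppa3, Esrrb and Tdh are near the floor there, and Zscan4f, Mdm2 and Cdkn1a are highest in Dnd1-KD (28.1, 231 and 86.3 FPKM).

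The endoderm, Hox and fibroblast lists passed camera as higher in Dnd1-KD with the preset correlation. The endoderm list had 10 of 16 members higher and none lower (11 and 1 adjusted over the list alone). For the list as a set, camera adjusted p = 0.00328, and adjusted p = 0.429 with an estimated correlation. Col4a1, a basement membrane collagen, rose from 10.5 ± 0.680 to 42.4 ± 2.77 FPKM (1.92 ± 0.10, adjusted p = 0.000145). The keratin Krt18 rose from 241 ± 23.6 to 522 ± 30.6 FPKM (1.11 ± 0.12, adjusted p = 0.00210). Of the 39 Hox genes listed 6 were tested, of which 4 rose (5 adjusted over the list alone). As a set it passed camera (adjusted p = 0.00611), and had an adjusted p = 0.429 with an estimated correlation. Hoxc13 was at 3.15 ± 0.581 FPKM against 0.914 ± 0.0495 FPKM (1.11 ± 0.12, adjusted p = 0.00209). The fibroblast or feeder list had 11 of 25 members higher and none lower (12 and 1 adjusted over the list alone). By camera the adjusted p = 0.0116, and adjusted p = 0.429 with an estimated correlation. The preset call ended without the filter on low values (adjusted p = 0.0530). Members that rose included the smooth muscle actin Acta2 (2.42 ± 0.27, adjusted p = 0.00239), the cross-linking enzyme Lox (1.34 ± 0.13, adjusted p = 0.00177) and Vim, an intermediate filament gene that ES cells also express (122 ± 14.6 FPKM in control and 302 ± 10.5 in Dnd1-KD). In the mesoderm list T, also called Brachyury, fell from 20.9 ± 3.97 to 1.71 ± 0.111 FPKM (−3.00 ± 0.27, adjusted p = 0.00149), while Hand1 rose (1.08 ± 0.12, adjusted p = 0.00223).

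Of the hypoxia and glycolysis list 16 of 32 members were lower and 5 higher in Dnd1-KD (18 and 6 adjusted over the list alone). The camera adjusted p was 0.00268, and adjusted p = 0.567 with an estimated correlation. Ldha, lactate dehydrogenase, fell from 753 ± 33.5 to 358 ± 37.0 FPKM (−1.07 ± 0.10, adjusted p = 0.00149). The hexokinase Hk2 fell from 45.8 ± 1.16 to 19.9 ± 2.22 FPKM (−1.17 ± 0.12, adjusted p = 0.00207). Ezh2, the catalytic subunit of PRC2 (chromosome 6, 47530139 to 47595341), was at 55.2 ± 0.286 FPKM against 65.4 ± 1.78 in control, a log2 difference of −0.24 ± 0.08 that did not pass (adjusted p = 0.0631). It passed with median-ratio scaling (adjusted p = 0.0373), with only the compared groups fitted (0.0215), and without the first or the second CDGC1 library (0.0483 and 0.0483). The PRC2 list had 5 of 13 members lower and 1 higher (6 and 1 adjusted over the list alone) and did not pass (camera adjusted p = 0.14). The cyclin gene Ccnd1 (chromosome 7, 144929931 to 144939925) fell from 77.1 ± 3.57 to 31.7 ± 12.1 FPKM (−1.31 ± 0.24, adjusted p = 0.00990), a call that ended without the first control library (adjusted p = 0.0524), without the second (0.0563) and with both averaged as 1 sample (0.0547).

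No call was made for the other 11 lists in Dnd1-KD. Their members higher and lower were 5 and 2 of 14 for mesoderm (camera adjusted p = 0.569), 3 and 1 of 12 for neural ectoderm (0.434), 4 and 2 of 12 for trophoblast (0.569), and 9 and 4 of 39 for imprinted genes (0.517). They were 5 and 8 of 20 for G1 cyclins and CDK inhibitors (0.517), 5 and 7 of 19 for the DNA methylation machinery (0.124), 6 and 3 of 20 for NODAL and ACTIVIN signalling (0.708), and 3 and 3 of 21 for the interferon response (0.434). They were 2 and 0 of 5 for testis somatic genes (0.764), 0 and 1 of 4 for leukocyte genes (0.434) and 1 and 0 of 4 for Y-linked genes (0.527), a list in which Xist was not among the tested genes. The DNA methylation list passed without the filter on low values (adjusted p = 0.0473) and with the filter at 5 FPKM (0.0356). Adjusted over the list alone, the members higher and lower became 4 and 3 for trophoblast, 1 and 2 for interferon, 2 and 1 for testis somatic and 0 and 0 for Y-linked genes, with no change in the other 7 lists. Median and mean change differed in sign for mesoderm, G1 cyclins and testis somatic genes.

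Over all genes, 4310 of 11905 tested differed between Dnd1-KD and control, 2466 higher and 1844 lower, of which 370 and 187 by at least 2-fold. Which direction had more genes depended on scaling, with 2213 higher and 2232 lower under quantile normalization and 2149 and 2238 under median-ratio scaling. The 2 control libraries lay closer together than the 2 of any other group, and the count fell to 1367 without the first of them, to 1630 without the second, to 1937 without the second Dnd1-KD library, and to 1469 with the controls averaged as 1 sample. The largest rises and falls by the fixed rule, such as Mpdu1 (listed at 0 in both control libraries, 56.5 and 57.6 FPKM in Dnd1-KD) and Fkbp8 (79.4 and 79.3 FPKM in control, listed at 0 in both Dnd1-KD libraries), all had a library at 0, which in these files can be a failed estimate.

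In CDGC1 24 of 28 genes of the naive and general pluripotency list were lower than in control, while Pou5f1 did not pass, and the list did not pass with an estimated correlation (adjusted p = 0.461). Dppa5a, Zfp42, Esrrb, Tdh and Dnmt3l were near the floor in CDGC1, and Fgf8, Fgf5 and Eomes, genes of the epiblast and early gastrula, were far above control. As sets, neither the primed or epiblast list (12 of 22 higher, 8 lower) nor the mesoderm list (7 and 3 of 14) passed (camera adjusted p = 0.147 and 0.342). The joint value of Dppa5a and Ooep, which are transcribed in naive ES cells and oocytes, was 1.90 ± 0.470 FPKM in CDGC1 (SD, n = 2) against 2287 ± 185 FPKM in control (−9.63 ± 0.23, adjusted p = 3.53e-06). Fgf8, a growth factor of the primitive streak, rose from 2.26 ± 0.309 to 143 ± 21.3 FPKM (5.46 ± 0.29, adjusted p = 4.23e-05).

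In the naive and general pluripotency list 24 of 28 members were lower in CDGC1 than in control and 2 higher (24 and 2 adjusted over the list alone). The list passed camera (adjusted p = 1.80e-10), with an adjusted p = 0.461 under an estimated correlation. The orphan nuclear receptor gene Esrrb was at 0.176 ± 0.0501 FPKM against 80.7 ± 3.04 (−6.12 ± 0.17, adjusted p = 6.39e-06). The threonine dehydrogenase gene Tdh was at 0.685 ± 0.276 against 239 ± 8.01 (−7.17 ± 0.18, adjusted p = 3.79e-06), and Dppa3 was at 0.0747 ± 0.0248 against 21.2 ± 0.331 (−4.37 ± 0.09, adjusted p = 1.75e-06). Zfp42, also called Rex1, was at 0.0220 and 0 FPKM in the 2 CDGC1 libraries and at 335 and 352 FPKM in control. Pou5f1 (989 ± 53.4 FPKM, adjusted p = 0.621) and Nanog (129 ± 10.7 against 131 ± 4.39 FPKM in control, adjusted p = 0.946) were the members that did not pass, and are named here after their values were seen.

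The primed or epiblast list went both ways in CDGC1, 12 of 22 members up and 8 down (13 and 8 adjusted over the list alone), and did not pass (camera adjusted p = 0.147). Zic2 rose from 6.67 ± 0.0278 to 51.7 ± 6.2 FPKM (2.77 ± 0.13, adjusted p = 2.52e-05). Pou3f1 rose from 15.9 ± 0.640 to 48.2 ± 1.82 FPKM (1.54 ± 0.08, adjusted p = 3.15e-05). Fgf5, measured together with an overlapping transcript, rose by a log2 difference of 4.66 ± 0.30 (adjusted p = 7.92e-05). Dnmt3l, a cofactor of de novo DNA methylation that the list also holds, fell from 273 ± 12.6 to 0.990 ± 0.151 FPKM (−7.11 ± 0.13, adjusted p = 1.55e-06). The Wnt effector Lef1 fell as well (−2.14 ± 0.11, adjusted p = 3.38e-05). Of the NODAL and ACTIVIN signalling list 13 of 20 members were higher and 4 lower (13 and 4 adjusted over the list alone). Camera gave an adjusted p = 0.0180, and an adjusted p = 0.42 with an estimated correlation. The activin antagonist Fst was at 98.9 ± 11.3 against 5.58 ± 0.704 FPKM (3.92 ± 0.24, adjusted p = 6.59e-05), whereas Gdf3 fell (−3.22 ± 0.16, adjusted p = 2.82e-05). The mesoderm list did not pass (camera adjusted p = 0.342), with 7 members up and 3 down of 14, also when adjusted over the list alone. Of its members, Eomes rose from 3.31 ± 0.319 to 74.2 ± 8.26 FPKM (4.12 ± 0.25, adjusted p = 6.71e-05). Wnt3 rose from 5.23 ± 0.319 to 44.4 ± 9.5 FPKM (2.85 ± 0.19, adjusted p = 9.38e-05).

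Of the germline list 22 of 28 members fell in CDGC1 and none rose (23 and 2 adjusted over the list alone). For the list as a set, camera adjusted p = 8.29e-09, and adjusted p = 0.42 with an estimated correlation. The germ cell RNA helicase gene Ddx4 went from 15.5 ± 0.0964 to 0.0179 ± 0.00592 FPKM (−4.02 ± 0.12, adjusted p = 7.28e-06). Tdrd12, of the piRNA pathway, went from 21.2 ± 1.63 to 0.105 ± 0.0780 FPKM (−4.33 ± 0.14, adjusted p = 8.43e-06). Sycp3, of the meiotic chromosome axis, and Mael were listed at 0 in both CDGC1 libraries, which can be a failed estimate, and stood at 41.8 ± 2.35 and 6.57 ± 0.0557 FPKM in control. All 13 tested members of the 2-cell-like list fell (13 adjusted over the list alone). As a set it passed camera (adjusted p = 8.68e-07), and had an adjusted p = 0.461 with an estimated correlation. Zscan4f was at 0.0152 ± 0.0113 against 9.70 ± 0.878 FPKM (−3.39 ± 0.20, adjusted p = 6.27e-05).

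The interferon, fibroblast and hypoxia lists passed camera as higher in CDGC1 with the preset correlation. The interferon list had 13 of 21 members higher and 1 lower (13 and 1 adjusted over the list alone). By camera the adjusted p = 0.000184, and adjusted p = 0.461 with an estimated correlation. The ubiquitin-like modifier gene Isg15 rose from 3.30 ± 0.477 to 46.1 ± 7.26 FPKM (3.45 ± 0.15, adjusted p = 1.79e-05). The RNA sensor gene Ifih1 rose from 0.256 ± 0.0214 to 5.64 ± 0.335 FPKM (2.40 ± 0.09, adjusted p = 1.42e-05). The fibroblast or feeder list had 17 of 25 members higher and 3 lower (17 and 3 adjusted over the list alone). The camera adjusted p was 0.000149, and adjusted p = 0.42 with an estimated correlation. Vim rose from 122 ± 14.6 to 801 ± 139 FPKM (2.70 ± 0.15, adjusted p = 5.10e-05). The collagen Col1a2 rose from 0.386 ± 0.00730 to 8.58 ± 0.0882 FPKM (2.79 ± 0.15, adjusted p = 4.49e-05), whereas Ctgf, a target of YAP signalling, fell (−3.13 ± 0.17, adjusted p = 4.92e-05). Of the hypoxia and glycolysis list 13 of 32 members rose and 3 fell (13 and 3 adjusted over the list alone). Camera gave an adjusted p = 0.0298, and an adjusted p = 0.527 with an estimated correlation. Ldha was at 1561 ± 123 against 753 ± 33.5 FPKM (1.05 ± 0.10, adjusted p = 0.000324). That preset call ended without the second CDGC1 library (adjusted p = 0.119), with quantile normalization (0.0737) and with units of a single gene symbol (0.0756).

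Ezh2 was at 73.0 ± 5.18 FPKM in CDGC1 and did not pass (log2 difference 0.16 ± 0.08, adjusted p = 0.158), but 8 of the 13 PRC2 genes fell and 1 rose (8 and 1 adjusted over the list alone). The list passed by little (camera adjusted p = 0.0473), with an adjusted p = 0.461 under an estimated correlation. The preset call ended without the first or second CDGC1 library (adjusted p = 0.0543 and 0.0612), without the first or second CDGC6 library (0.0591 and 0.0590), with a pseudocount of 0.1 (0.0562), without the filter on low values (0.0546), with the replicate block (0.0692), with only the compared groups fitted (0.0604) and with units of a single gene symbol (0.0756). Mtf2, an accessory subunit of PRC2, fell from 79.0 ± 1.01 to 26.3 ± 1.09 FPKM (−1.55 ± 0.06, adjusted p = 1.70e-05). The core subunit gene Eed fell from 126 ± 2.64 to 52.1 ± 1.90 FPKM (−1.26 ± 0.06, adjusted p = 3.21e-05). Ccnd1 was at 60.8 ± 6.73 FPKM (−0.34 ± 0.24, adjusted p = 0.279) and passed without the first Dnd1-KD library or without the second (0.0451 and 0.0448). The joint Dnd1 and Hars value was 76.4 ± 7.00 FPKM (0.22 ± 0.08, adjusted p = 0.0669), and passed without the second CDGC1 library (0.0218). Imprinted genes moved in both directions, 16 higher and 13 lower of 39, both counts the same adjusted over the list alone, with no call for the list (camera adjusted p = 0.576). The median of that list was above 0 and its mean below. Meg3, a maternally expressed RNA, fell from 98.8 ± 2.87 to 0.708 ± 0.829 FPKM (−5.96 ± 0.32, adjusted p = 4.45e-05). The growth factor receptor adaptor gene Grb10 fell from 45.0 ± 0.0783 to 0.644 ± 0.179 FPKM (−4.81 ± 0.15, adjusted p = 8.43e-06).

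Lists without a call in CDGC1 were, with their members higher and lower, endoderm (4 and 7 of 16, camera adjusted p = 0.898), neural ectoderm (4 and 7 of 12, 0.266), trophoblast (1 and 6 of 12, 0.129), Hox genes (0 and 4 of 6, 0.147) and G1 cyclins and CDK inhibitors (5 and 8 of 20, 0.460). The others were the DNA methylation machinery (3 and 8 of 19, 0.173), the p53 response (2 and 10 of 24, 0.14), testis somatic genes (3 and 2 of 5, 0.460), leukocyte genes (1 and 3 of 4, 0.266) and Y-linked genes (2 and 0 of 4, 0.222). Without the first CDGC1 library the p53 list (adjusted p = 0.0218) and the trophoblast list (0.0218) passed. Adjusted over the list alone, the members higher and lower became 7 and 8 for endoderm and 5 and 9 for G1 cyclins, with no change in the other 8 lists. The endoderm median was above 0 although camera ranked the list as lower. The Hox gene Hoxd9 and the testis list's Gata4, both under 1 FPKM in CDGC1 and control, changed direction with quantile normalization. In the neural list Tubb3 fell from 38.2 ± 0.0110 to 5.41 ± 0.915 FPKM (−2.62 ± 0.14, adjusted p = 4.56e-05). Of the testis list Clu, which is also expressed widely elsewhere, rose from 30.4 ± 1.21 to 94.2 ± 17.5 FPKM (1.59 ± 0.18, adjusted p = 0.000762).

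Over all genes, 6011 of 11905 differed between CDGC1 and control, 2800 higher and 3211 lower, of which 792 and 1145 by at least 2-fold. The balance turned to 3134 higher and 2749 lower with quantile normalization and to 2201 and 2154 with the filter at 5 FPKM. Leaving out any 1 library left 4094 to 6065. Among the 10 largest rises by the fixed rule only Hprt and Fgf8 had values above 0 in every library. The 10 largest falls included Rps4l, a ribosomal protein paralogue whose reads can be shared with relatives (−7.98 ± 0.09, adjusted p = 5.06e-07), and Pla2g1b (−6.97 ± 0.34, adjusted p = 3.00e-05).

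In CDGC6 12 of 22 primed or epiblast genes, 7 of 20 NODAL and ACTIVIN signalling genes and 16 of 32 hypoxia and glycolysis genes were higher than in control ES cells, 14 of 24 p53 response genes were lower, and 24 of 28 pluripotency genes did not pass. None of these lists passed with an estimated inter-gene correlation. Fgf8 was at 32.6 ± 14.8 FPKM in CDGC6 (SD, n = 2) against 2.26 ± 0.309 FPKM in control (3.29 ± 0.29, adjusted p = 0.00201). Lefty1 and Lefty2, antagonists and targets of NODAL that were measured together, rose from 53 ± 3.03 to 339.8 ± 55.3 FPKM (2.65 ± 0.26, adjusted p = 0.00267). Mdm2 fell from 96.7 ± 1.68 to 37.0 ± 3.36 FPKM (−1.36 ± 0.10, adjusted p = 0.00118).

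Of the naive and general pluripotency list 24 of 28 members did not pass in CDGC6, 2 rose and 2 fell, with the same counts adjusted over the list alone, and the list had no call (camera adjusted p = 0.547). Dppa3 rose from 21.2 ± 0.331 to 53.3 ± 4.76 FPKM (1.29 ± 0.09, adjusted p = 0.000938). The primed or epiblast list had 12 of 22 members higher and 2 lower, also when adjusted over the list alone. For the list as a set, camera adjusted p = 0.000137, and adjusted p = 0.347 with an estimated correlation. Zic2 was at 27.8 ± 1.13 against 6.67 ± 0.0278 FPKM (1.91 ± 0.13, adjusted p = 0.000938). Zic5 was at 12.7 ± 0.346 against 4.25 ± 0.0993 FPKM (1.38 ± 0.09, adjusted p = 0.000938). NODAL and ACTIVIN signalling genes had 7 of 20 members higher and none lower (7 and 1 adjusted over the list alone). As a set it passed camera (adjusted p = 0.0350), and had an adjusted p = 0.347 with an estimated correlation. This preset call ended without the first CDGC6 library (adjusted p = 0.0952), with the filter at 5 FPKM (0.0693), with only the compared groups fitted (0.0525) and with units of a single gene symbol (0.0762). In the germline list 5 of 28 rose and 4 fell (6 and 7 adjusted over the list alone) with no call (camera adjusted p = 0.563). Prdm1, which specifies germ cells, rose from 1.68 ± 0.0238 to 4.82 ± 0.213 FPKM (1.12 ± 0.10, adjusted p = 0.00187).

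Of the hypoxia and glycolysis list 16 of 32 members were higher in CDGC6 and none lower (22 and 1 adjusted over the list alone). By camera the adjusted p = 7.95e-08, and adjusted p = 0.347 with an estimated correlation. Pgk1 was at 904 ± 81.2 against 435 ± 19.7 FPKM (1.05 ± 0.08, adjusted p = 0.00139). Vegfa was at 8.98 ± 0.371 against 2.87 ± 0.0647 FPKM (1.37 ± 0.17, adjusted p = 0.00577). The interferon list had 7 of 21 members higher and 1 lower (12 and 1 adjusted over the list alone). The camera adjusted p was 0.00134, and adjusted p = 0.402 with an estimated correlation. Isg15 was at 8.26 ± 0.965 FPKM (1.11 ± 0.15, adjusted p = 0.00696, and 0.0553 without the first control library). The fibroblast or feeder list had 10 of 25 higher and 2 lower (13 and 5 adjusted over the list alone). Camera gave an adjusted p = 0.00195, and an adjusted p = 0.347 with an estimated correlation. With the filter at 5 FPKM the preset call ended (adjusted p = 0.350). Col1a2 rose to 6.89 ± 1.73 FPKM (2.49 ± 0.15, adjusted p = 0.000609), and the joint value of S100a3 and S100a4 from 3.28 ± 0.455 to 28.7 ± 11.3 FPKM (2.74 ± 0.26, adjusted p = 0.00230).

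Of the p53 response list 14 of 24 members were lower in CDGC6 and none higher (18 and 0 adjusted over the list alone). For the list as a set, camera adjusted p = 2.84e-08, and adjusted p = 0.312 with an estimated correlation. Pmaip1, also called Noxa, fell from 19.3 ± 0.658 to 7.87 ± 0.348 FPKM (−1.20 ± 0.10, adjusted p = 0.00166). The 2-cell-like list had 11 of 13 tested members lower (13 adjusted over the list alone). As a set it passed camera (adjusted p = 7.95e-08), and had an adjusted p = 0.347 with an estimated correlation. Tcstv3 was at 0.623 ± 0.0386 against 2.02 ± 0.0612 FPKM (−0.90 ± 0.09, adjusted p = 0.00259). Of the trophoblast list 10 of 12 members fell, also when adjusted over the list alone. By camera the adjusted p = 4.41e-07, and adjusted p = 0.312 with an estimated correlation. Of these, Sct was at 0.615 ± 0.0566 against 2.77 ± 0.209 FPKM (−1.22 ± 0.10, adjusted p = 0.00185). Hand1 was at 0.366 ± 0.0402 against 2.20 ± 0.353 FPKM (−1.23 ± 0.12, adjusted p = 0.00243). Endoderm had 5 of 16 lower and none higher (6 and 1 adjusted over the list alone). The camera adjusted p was 0.0444, and adjusted p = 0.347 with an estimated correlation. Krt18 fell to 63.7 ± 7.40 FPKM (−1.90 ± 0.12, adjusted p = 0.000614). The preset endoderm call ended without the first or second CDGC6 library (adjusted p = 0.0781 and 0.0642), without the second control library (0.0703), without the first or second Dnd1-KD library (0.0613 and 0.0613), with the filter at 5 FPKM (0.0693), with the replicate block (0.0608), with only the compared groups fitted (0.0539) and with units of a single gene symbol (0.0762). Of the Hox genes 3 of 6 tested fell, also when adjusted over the list alone. Camera gave an adjusted p = 0.0350, and an adjusted p = 0.355 with an estimated correlation. That preset call ended without the first CDGC6 library (0.134), without the filter on low values (0.293), with a pseudocount of 5 (0.0652) and with units of a single gene symbol (0.0762). Hoxc13 fell, a call that ended without the first or second CDGC6 library (adjusted p = 0.107 and 0.0964), without the first or second control library (0.153 and 0.186), with the controls averaged (0.173), with a pseudocount of 5 (0.104) and with the replicate block (0.0574). The call for Hoxb9, measured together with Gm53, ended without the second control library (0.0971), with the controls averaged (0.0659) and with only the compared groups fitted (0.0578).

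Ezh2 did not pass in CDGC6 (78.7 ± 6.28 FPKM, 0.26 ± 0.08, adjusted p = 0.0719), nor did Ccnd1 (79.0 ± 5.78 FPKM, 0.03 ± 0.24, adjusted p = 0.940). Dnd1 was listed at 0, and the Hars entry was at 60.1 and 63.4 FPKM in the CDGC6 libraries against 65.8 and 65.0 FPKM in control. Imprinted genes again went both ways, 14 higher and 11 lower of 39 (17 and 12 adjusted over the list alone), with no call (camera adjusted p = 0.402). Grb10 fell from 45.0 ± 0.0783 to 9.00 ± 2.05 FPKM (−2.22 ± 0.15, adjusted p = 0.000938), and Magel2, a paternally expressed gene, rose from 0.690 ± 0.0716 to 5.39 ± 0.937 FPKM (1.91 ± 0.14, adjusted p = 0.00118). The lists of PRC2 (0 higher and 2 lower of 13, camera adjusted p = 0.120), mesoderm (3 and 2 of 14, 0.916), neural ectoderm (1 and 2 of 12, 0.444) and G1 cyclins and CDK inhibitors (0 and 2 of 20, 0.440) had no call. The same held for the DNA methylation machinery (2 and 3 of 19, 0.486), testis somatic genes (0 and 1 of 5, 0.292), leukocyte genes (0 and 2 of 4, 0.188, and 0.0441 with the filter at 5 FPKM) and Y-linked genes (2 and 0 of 4, 0.188). Adjusted over the list alone, the members higher and lower became 4 and 3 for mesoderm, 0 and 1 for PRC2 and 2 and 4 for the DNA methylation machinery, with no change in the other 5.

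Over all genes, 2218 of 11905 differed between CDGC6 and control, 1001 higher and 1217 lower, of which 228 and 172 by at least 2-fold. The balance turned to more genes higher than lower without the first control library (220.0 and 206), without the second (270.0 and 227), without the second CDGC6 library (716 and 616) and with the controls averaged (233 and 208). This count rested on single libraries: it was 426 without the first control library, 497 without the second, 1450 without the first CDGC6 library, 1332 without the second, and 441 with the controls averaged as 1 sample. Of the 98 genes that the naming rule picked and that passed in CDGC6, 36 lost their call without the first control library and 35 without the second. Among the largest falls, Mid1, an X-linked gene, was at 4.26 ± 1.39 FPKM against 404 ± 106 in control and 387 ± 83.7 in Dnd1-KD (−6.27 ± 0.26, adjusted p = 9.02e-05).

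**Figure D3:**
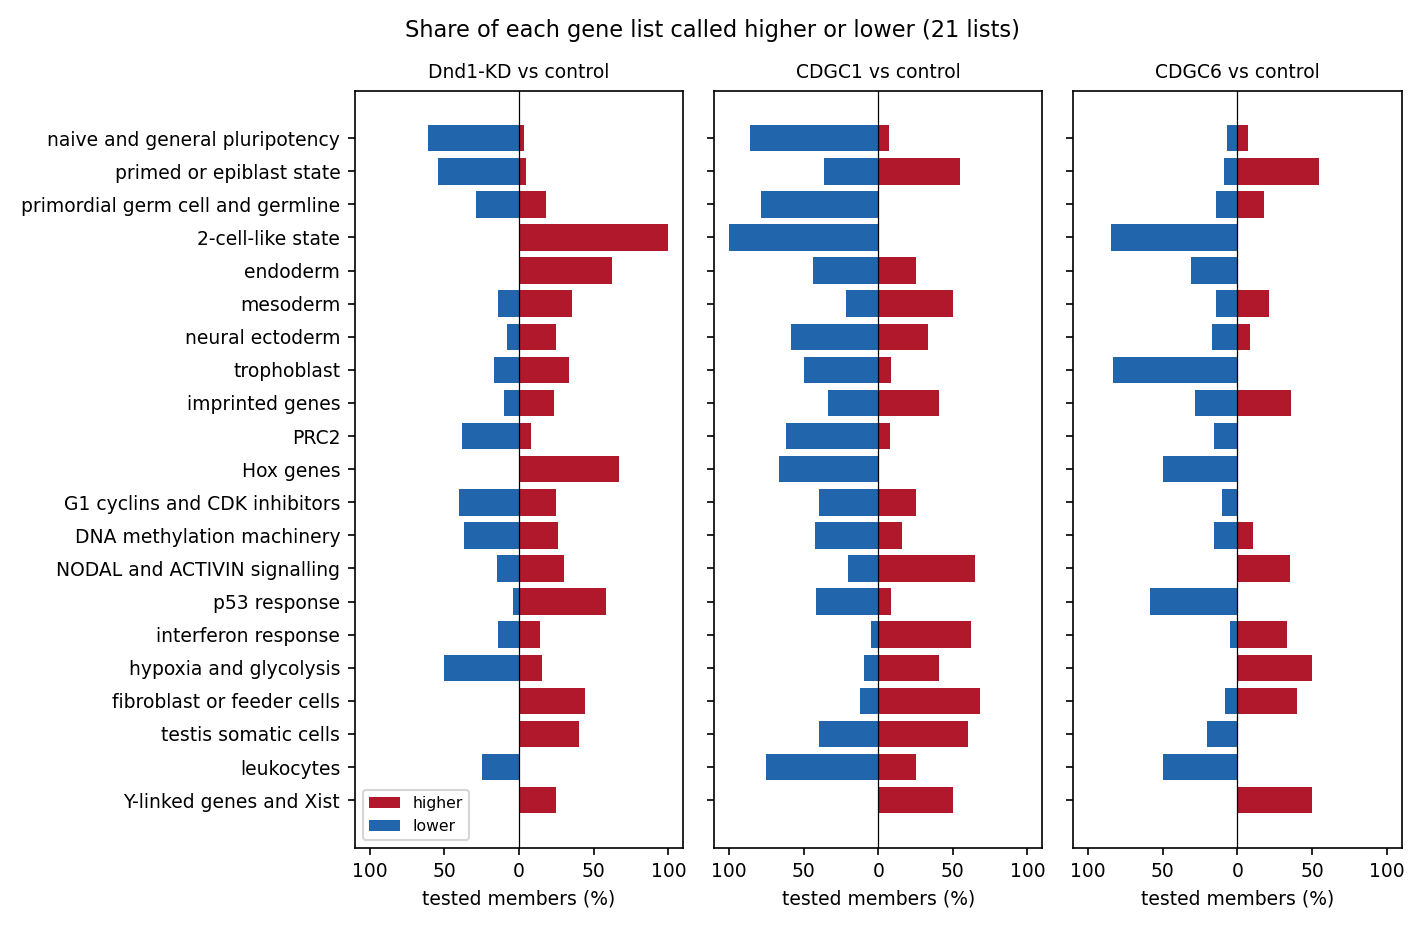
Share of the measured members of each of 21 gene lists that passed as higher (red, to the right) or lower (blue, to the left) against control ES cells, in percent of members (horizontal axis), in 3 panels for Dnd1-KD, CDGC1 and CDGC6. All 13 measured 2-cell-like genes are higher in Dnd1-KD and all 13 lower in CDGC1, and most pluripotency genes are lower in Dnd1-KD (17 of 28) and CDGC1 (24 of 28) and 2 of 28 in CDGC6, a list that passed camera in none of the 3 with an estimated correlation; bars of lists under 10 members rest on few genes, and Hoxd9 and Gata4 turn direction with quantile normalization in CDGC1.

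Averaged over both derived lines, 4626 genes differed from control, 2070 higher and 2556 lower (876 by at least 2-fold; 2286 higher and 2272 lower with quantile normalization), and 2098 did so without the first control library, 2164 without the second and 2097 with the controls averaged. Of the genes with no library at 0, the largest rises were those of Hprt (6.49 ± 0.07, adjusted p = 3.87e-07), Fgf8 (4.38 ± 0.25, adjusted p = 0.000138) and Fgf5 (3.68 ± 0.26, adjusted p = 0.000247). Among the falls were Mid1 (−6.00 ± 0.22, adjusted p = 2.67e-05) and Grb10 (−3.51 ± 0.13, adjusted p = 2.67e-05). Dnd1 was listed at 0 in the libraries of both lines and of control. Ezh2 did not pass (0.21 ± 0.07, adjusted p = 0.0592), except with median-ratio scaling (0.0489), with the replicate block (0.0477) and without the first CDGC1 (0.0378) or first CDGC6 library (0.0388), and Ccnd1 did not pass (−0.16 ± 0.21, adjusted p = 0.588). Camera called 11 of the 21 lists. Lower were pluripotency (23 of 28 members, adjusted p = 1.22e-09), germline (22 of 28, 3.14e-07), 2-cell-like (13 of 13, 1.08e-07), trophoblast (8 of 12, 0.000121), PRC2 (7 of 13, 0.0265) and p53 response (15 of 24, 4.74e-05). Higher were primed or epiblast (12 of 22, 0.0267), NODAL and ACTIVIN (11 of 20, 0.00571), interferon (12 of 21, 4.16e-05), hypoxia and glycolysis (18 of 32, 4.16e-05) and fibroblast genes (17 of 25, 7.20e-05). With an estimated correlation none of the 11 held (adjusted p = 0.326 to 0.396), and the primed list also ended without either CDGC1 library (0.0540 and 0.0666). The other 10 lists had no call, with members higher and lower of 3 and 6 for endoderm (camera adjusted p = 0.408), 6 and 3 for mesoderm (0.361), 4 and 6 for neural ectoderm (0.274), 16 and 15 for imprinted (0.848) and 0 and 4 for Hox genes (0.0562). They were 3 and 8 for G1 cyclins (0.408), 4 and 7 for DNA methylation (0.238), 0 and 1 for testis somatic (0.728), 0 and 2 for leukocyte (0.238) and 2 and 0 for Y-linked genes (0.0539). The imprinted median was above 0 and its mean below. Of these 10 the Hox list passed without the second CDGC6 library (0.0427), without the first or second Dnd1-KD library (0.0471 and 0.0472), with a pseudocount of 0.1 (0.0484) and with only the compared groups fitted (0.0434). The Y-linked list passed without the second CDGC6 library (0.0377), without the first control library (0.0257), with the controls averaged (0.0477) and with median-ratio scaling (0.0498), and the mesoderm list with the filter at 5 FPKM (0.0185).

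Adjusted over the list alone, members higher and lower in the derived lines became 2 and 24 for pluripotency, 13 and 7 for primed or epiblast, 0 and 9 for trophoblast, 2 and 8 for PRC2 and 4 and 8 for G1 cyclins. They became 1 and 17 for p53, 13 and 1 for interferon, 20 and 1 for hypoxia and 17 and 3 for fibroblast genes, with no change in the other 12 lists. A mean of 2 lines is not a replicated sample of derived lines, and the pluripotency and germline lists passed in CDGC1, did not pass in CDGC6, and differed between the lines. With an estimated correlation neither passed in CDGC1 (adjusted p = 0.461 and 0.42) or between the lines (0.528 for both).

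The direct comparison of the 2 derived lines, which share genotype, strain and passage range by the labels, tested whether their changes from control differed. In CDGC1 23 of 28 pluripotency genes, 24 of 28 germline genes and the imprinted RNA Meg3 were lower than in CDGC6, and 11 of 21 interferon response genes, Apln and Igfbp3 were higher. Dppa3 was at 0.0747 ± 0.0248 FPKM in CDGC1 and 53.3 ± 4.76 FPKM in CDGC6 (SD, n = 2; −5.66 ± 0.09, adjusted p = 1.10e-06). Meg3 was at 0.708 ± 0.829 and 213 ± 6.63 FPKM (−7.06 ± 0.32, adjusted p = 3.11e-05). Apln, a peptide ligand, was at 62.5 ± 0.282 and 4.94 ± 0.352 FPKM (3.42 ± 0.09, adjusted p = 5.96e-06). The growth factor binding protein gene Igfbp3 was at 634 ± 192 and 79.7 ± 21.1 FPKM (2.97 ± 0.24, adjusted p = 0.000259).

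Camera called 5 lists between the lines. Lower in CDGC1 were pluripotency (23 of 28 members lower, none higher, adjusted p = 1.02e-12), germline (24 lower and 1 higher of 28, 6.55e-11) and 2-cell-like genes (9 of 13 lower, none higher, 0.000289). Higher were p53 response (11 higher and 4 lower of 24, 0.0304) and interferon genes (11 higher and 1 lower of 21, 0.00642). With an estimated correlation each of the 5 had an adjusted p = 0.528. The p53 call also ended without the first CDGC1 library (adjusted p = 0.115), without the first CDGC6 library (0.0830) and with quantile normalization (0.0806), the interferon call without the second CDGC1 library (0.0763), and the 2-cell-like call with quantile normalization (0.0631). Adjusted over the list alone, the members lower and higher were 24 and 0 for pluripotency, 24 and 1 for germline, 10 and 0 for 2-cell-like, 4 and 12 for p53 and 2 and 13 for interferon genes. Pmaip1 was at 43.2 ± 1.85 FPKM in CDGC1 and 7.87 ± 0.348 in CDGC6 (2.32 ± 0.10, adjusted p = 2.48e-05). Of the primed or epiblast list 9 members were higher and 9 lower, with no call (camera adjusted p = 0.938), and fibroblast genes had 9 higher and 4 lower of 25 (camera adjusted p = 0.0707), a list that passed without the second CDGC6 library (0.00858) and without the filter (0.0116). The other lists had no call, with members higher and lower of 6 and 4 for endoderm (0.229), 5 and 2 for mesoderm (0.342), 4 and 7 for neural ectoderm (0.342), 5 and 2 for trophoblast (0.398), 19 and 13 for imprinted (0.881) and 1 and 5 for PRC2 genes (0.229). They were 0 and 0 for Hox (0.694), 5 and 6 for G1 cyclins (0.694), 3 and 10 for DNA methylation (0.159), 9 and 4 for NODAL (0.342), 4 and 8 for hypoxia (0.342), 3 and 2 for testis somatic (0.398), 1 and 2 for leukocyte (0.638) and 2 and 1 for Y-linked genes (0.496).

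In the lists without a call between the lines, members higher and lower became, adjusted over the list alone, 8 and 4 for endoderm, 5 and 3 for mesoderm, 5 and 3 for trophoblast, 19 and 15 for imprinted and 9 and 5 for NODAL and ACTIVIN genes, with no change in the other 11 lists. The primed and the imprinted lists each had a median above 0 and a mean below, and camera ranked the primed list as lower.

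Ezh2 (−0.11 ± 0.08, adjusted p = 0.329) and Ccnd1 (−0.37 ± 0.24, adjusted p = 0.245) did not differ between the lines beyond the test, though Ccnd1 passed without the first or the second Dnd1-KD library (0.0375 and 0.0372). The joint Dnd1 and Hars value was higher in CDGC1 (0.30 ± 0.08, adjusted p = 0.0251), a value of Hars, since Dnd1 was listed at 0 in both lines. That call ended without the first CDGC1 library (0.0797), without the first or second CDGC6 library (0.0980 and 0.0554), without the first or second control library (0.0544 and 0.0543), with both controls averaged (0.0543) and with only these lines fitted (0.0846). Over all genes 5606 of 11905 differed between the lines, 2738 higher and 2868 lower in CDGC1 (624 and 1039 by at least 2-fold), and 4465 to 5723 did so when 1 library was left out. More genes were higher than lower with quantile normalization (3212 and 2433), median-ratio scaling (2866 and 2805), the filter at 5 FPKM (2238 and 1895) and without the first CDGC1 library (2532 and 2343).

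Genes that passed in the same direction in 2 comparisons were counted to set the knockdown beside the derived lines. Dnd1-KD and CDGC1 shared 677 rises and 620 falls, where independent lists of these sizes would share 580.0 and 497, and 1143 genes went opposite ways against 1099. Dnd1-KD and CDGC6 shared 164 rises and 197 falls, where independent lists would share 207 and 189, and 748 genes went opposite ways against 407 for independent lists. CDGC1 and CDGC6 shared 603 rises and 732 falls, against 235 and 328, with 256 opposite against 556. All 3 counts rest on the control libraries. Shared in the same direction were 1297 genes for Dnd1-KD and CDGC1 (351 without the first control library, 453 without the second, 607 without the second Dnd1-KD library). For Dnd1-KD and CDGC6 they were 361 (97, 143 and 189 without the same libraries), and for the 2 lines 1335 (291 and 354 without each control library, and 848 without the first CDGC6 library).

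Comparisons against the same control libraries share their chance values. In 100 simulated sets of unchanged groups, at most 1 gene was called in both comparisons of a pair, and the correlation of log2 differences averaged 0.50 for Dnd1-KD with CDGC1, 0.501 for Dnd1-KD with CDGC6 and 0.491 for CDGC1 with CDGC6. No gene was changed in these sets, so their low count is no measure for the observed overlaps. They also gave all groups the same spread per gene. The control libraries lay closer together (median absolute log2 difference 0.0530, against 0.107 to 0.153 in the other groups), so the simulated covariance may be too high. The observed correlations across genes were 0.178, 0.141 and 0.441. The covariance was 0.108 against 0.0429 simulated for Dnd1-KD with CDGC1, 0.0485 against 0.0426 for Dnd1-KD with CDGC6, and 0.238 against 0.0418 for CDGC1 with CDGC6, differences of 0.0656, 0.00585 and 0.196. Splitting the controls would leave 1 library in each part, so part of each excess may come from the shared controls.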

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

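All tests of explanations in this part were chosen after the results were seen. The comparison between the derived lines was planned.

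The derived lines differed from each other in their change from control. Between them 5606 genes passed, and 256 genes passed against control in opposite directions. Lists that differed were pluripotency (adjusted p = 1.02e-12), germline (adjusted p = 6.55e-11), 2-cell-like (adjusted p = 0.000289), p53 response (adjusted p = 0.0304) and interferon genes (adjusted p = 0.00642), none of which passed with an estimated correlation (adjusted p = 0.528 for each). Of the 165 genes named in the comparisons of the 2 lines with control, 117 differed between the lines, against 5606 of all 11905 genes tested. Most of the 165 were picked for large changes or small p in these same libraries, so their share is not added support. The joint Dnd1 and Hars value differed by a log2 difference of 0.30 and lost its call without the first CDGC1 library, without each CDGC6 library and without each control library (adjusted p = 0.0543 to 0.0980).

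Transcripts without a gene name gave a signal in libraries of other groups and none in control. At least 5 FPKM in both libraries, with none in control, was found at 2 loci in CDGC1, 2 in CDGC6 and 1 in Dnd1-KD. The reverse, at least 5 FPKM in both controls and none in the group, was found at 47, 6 and 3 loci. Only longer loci that overlapped no named entry were counted. The CDGC1 libraries held fewer entries without a gene name (3000 and 4793) than the control libraries (9089 and 5508), so a locus without an entry there need not be silent. Inside Dnd1 an unnamed transcript had 2.80 FPKM in the second CDGC6 library.

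In CDGC1 24 of 28 pluripotency genes were lower while Pou5f1 did not pass, and 17 of 25 fibroblast-list genes were higher and 3 lower, lists that did not pass with an estimated correlation (adjusted p = 0.461 and 0.42). Other cells that express none of the pluripotency genes would, if mixed into the CDGC1 cultures, lower them by 1 common share. Against this, 11 of 26 members with at least 10 FPKM in control lay above the list's median log2 change of −3.82 with their whole 95% interval. Cells that express part of the list, such as Pou5f1 and Nanog, would not lower it by 1 share, so this test cannot exclude them. Genotype, strain and passage range, which both derived lines share, do not account for that fall alone, since 23 of 28 members were lower in CDGC1 than in CDGC6. The fibroblast list was higher in CDGC6 too (10 of 25 members, camera adjusted p = 0.00195, 0.350 with the filter at 5 FPKM and 0.347 with an estimated correlation) and did not pass between the lines (0.0707, but 0.00858 without the second CDGC6 library and 0.0116 without the filter), so what both lines share stays open for it. Feeder or fibroblast RNA cannot be told apart from expression by the line itself for that list, since all 3 collagens examined rose in CDGC1 (Col1a1 from 3.31 to 17.3 FPKM, Col1a2 from 0.386 to 8.58 and Col3a1 from 0.628 to 1.92) while the highest reached 2.16% of Vim.

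In Dnd1-KD 17 of 28 pluripotency genes were lower, and 13 of 13 tested 2-cell-like and 14 of 24 p53 response genes were higher. These lists did not pass camera with an estimated correlation (adjusted p = 0.496, 0.429 and 0.429). Sequencing depth was argued against for the 2-cell-like and p53 lists, since the median log2 change over all members was at least 1.03 and 0.55 in both pairs of libraries of like depth, against at most 0.21 and 0.07 between 2 libraries of 1 group. For the pluripotency list the medians in these pairs were −0.45 and −0.71, the first at nearly equal depth (18.0 M and 17.7 M fragments). Libraries of unlike depth differed by −0.01 in control but by 0.32 in Dnd1-KD. Both pairs exceeded these differences, but the smaller fell short of 2 times the larger of them, the limit set for this test. Depth therefore cannot be told apart from a difference between the groups by that limit. Differentiated cells mixed into the cultures cannot be told apart from a change within the ES cells for the pluripotency genes, since only 2 of 26 members lay above the list's median log2 change of −0.52 with their whole interval and 4 below. Lower Dnd1 in the knockdown libraries cannot be told apart from other differences between the cultures, since 0 libraries had a Dnd1 value of its own.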

How the results depend on the processing

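Averaging the controls, leaving zeros at overlapping genes out and using units of 1 symbol were chosen after the data were seen, and the other settings were planned. Of the results of named genes, 11693 were unchanged, 405 lost a call, 49 gained one and 5 reversed direction with a call before or after. A turn of direction without a call in either setting was counted as unchanged. For lists the numbers were 2304, 80, 21 and 0. The reversals of named genes all came with quantile normalization, as log2 differences of 0.25 for Hoxd9 and 0.0766 for Gata4 in CDGC1, 0.0134 for Hoxd9 in the mean of the lines, and 0.41 for Hoxc13 and 0.48 for Hoxd9 between the lines, all low in most libraries; the cause was not tested. Over all genes that passed, the sign turned with quantile normalization in 2 genes in Dnd1-KD, 78 in CDGC1, 0 in CDGC6, 5 in the mean of the lines and 82 between the lines, and with the highest entry per gene in 13, 11, 4, 12 and 6. At least 2-fold changes numbered 557 in Dnd1-KD, 1937 in CDGC1, 400 in CDGC6, 876 in the mean of the lines and 1663 between the lines, fewer by the construction of that setting. With the control libraries averaged as 1 sample 1469 genes passed in Dnd1-KD, 441 in CDGC6 and 2097 in the mean of the lines, with fewer samples in the fit. With an estimated inter-gene correlation camera called 0 lists in each of the 5 comparisons (preset 8 in Dnd1-KD, 8 in CDGC1, 10 in CDGC6, 11 in the mean and 5 between the lines), while at an unadjusted p below 0.05 it called 1, 0, 2, 2 and 1, and fry called 15, 21, 18, 19 and 19. With quantile normalization camera called 3 lists between the lines; the cause was not tested.

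Leaving out 1 library (a lone library was assumed to vary like the other groups) gave 1367 to 4931 genes in Dnd1-KD, 4094 to 6065 in CDGC1, 426 to 2899 in CDGC6, 2098 to 4951 in the mean of the lines and 4465 to 5723 between the lines. Most reductions came without the first control library (1367, 426 and 2098) or the second (1630, 497 and 2164), with 1937 in Dnd1-KD without its second library, and 1450 and 1332 in CDGC6 without its first or second library. Camera then called 8 to 9, 6 to 9, 7 to 10, 10 to 13 and 4 to 6 lists. Genes shared in direction ranged from 351 to 1469 for Dnd1-KD and CDGC1, from 97 to 492 for Dnd1-KD and CDGC6, and from 291 to 1665 for the derived lines. With the replicate block, 3925 genes passed in Dnd1-KD, 5783 in CDGC1, 1655 in CDGC6, 4272 in the mean and 5366 between the lines, of which 3801, 5655, 1596, 4155 and 5222 passed without it, and the list calls of PRC2 in CDGC1 (adjusted p = 0.0692) and endoderm in CDGC6 (0.0608) ended. First libraries deviated from their group means with correlations across genes of −0.08 to 0.0009 between groups, but of 0.146 between control and Dnd1-KD. A pairing of libraries by number is therefore not excluded for these 2 groups, whose like-numbered libraries were also of like depth. Count models were not run, since the files hold no counts. Simulated 1.5-fold changes were recovered in 0% to 24.0% of units, and whether depth or the spread between 2 libraries limits this was not tested.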

Other observations

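The tests of maternally and paternally expressed genes in this part were chosen after the results were seen.

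Some genes outside the planned lists or within the Y-linked list differed between the lines. Kdm5d, a Y-linked histone demethylase, was at 5.12 ± 0.423 FPKM in CDGC1 (SD, n = 2), against 0.0169 ± 0.00836 FPKM in CDGC6, 0.0147 ± 0.00386 FPKM in control and 0.0280 ± 0.0123 FPKM in Dnd1-KD. The Y-linked genes Eif2s3y and Uty had values in every group, with Eif2s3y at 52.9 ± 0.106 FPKM in CDGC6 and 40.7 ± 2.03 FPKM in control, and Uty at 8.70 ± 1.02 and 8.37 ± 1.01 FPKM. Id1 and Id2, targets of BMP signalling, were lowest in CDGC6. Id1 was at 16.8 ± 2.20 FPKM there against 102 ± 7.75 in control (−2.54 ± 0.41, adjusted p = 0.0125), and Id2 at 10.7 ± 2.45 against 55.1 ± 5.29 FPKM (−2.28 ± 0.30, adjusted p = 0.00694). The Id1 call ended without the first CDGC6 library (adjusted p = 0.0564), without either control library (0.0778 and 0.0662) and with the controls averaged (0.0767), and the Id2 call without the first control library (0.0517).

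Imprinted genes moved in both directions in the derived lines. A hypothesis that maternally expressed genes fall relative to paternally expressed genes in CDGC1 was tested on 12 maternally and 21 paternally expressed units. Their mean log2 changes were −3.06 and 0.73, a difference of −3.78 (two-sided permutation test with 100000 resamples, p = 0.000120, adjusted over 3 tests 0.000360). In CDGC6 the difference was −0.93 (permutation p = 0.0789), and in Dnd1-KD −0.44 (permutation p = 0.0187, adjusted over the 3 tests 0.0281). Without chromosome 12, which holds the Meg3 region, the permutation p, not adjusted, was 0.00135 in CDGC1, 0.00747 in CDGC6 and 0.0534 in Dnd1-KD. In CDGC6 that step took out maternally expressed units that went the other way (Meg3 1.10, Rian 2.17 and Mirg 0.89), so the smaller p there is not added support. Over all units in CDGC6, 3 maternally expressed units passed as higher and 6 as lower, and 11 paternally expressed units as higher and 5 as lower. A candidate explanation in CDGC1 is a changed parental imprint, but genes of 1 cluster are not independent, and 4 paternally expressed genes fell. It was not tested, since these expression values show neither methylation nor the allele of origin.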
